A study of Mus musculus with 6 samples.

How the data were processed

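RNA was taken from 6 mouse hearts and sequenced, 3 wild type and 3 with an Arrdc4 knockout made by CRISPR-Cas9, per the labels. Total RNA was purified on Qiagen columns and libraries were made with a NEBNext Ultra II RNA kit, per the labels' protocols. Age, litter, sex, collection time and sequencing run are not given in the sources used here. The deposited table holds whole-number read counts per gene and sample, not normalized. STAR, featureCounts, Subread 1.5.2, DESeq2 and the mouse build GRCm38.p6 are named in the submitters' processing notes, without the role of each. The annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Values of overlapping or antisense genes and of near-identical families, such as ribosomal protein, histone and interferon-stimulated genes, are therefore uncertain where reads can be shared.

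The table has 49315 Ensembl gene identifiers, of which 48970 matched a symbol and 345 did not; the latter took 0.0147% to 0.0173% of the counts. Every column was matched to its sample by name. Totals ran from 29974501 to 41036626 counts per library. Reads carry no molecular identifiers, so counting intervals cover counting error only. Coordinates, exons, exon lengths and GC content came from GENCODE release M21 on GRCm38, and 99.8% of the tested genes had a length and a GC value. Groups and replicate numbers were taken from the sample titles and genotype labels. No 2 libraries agreed within sampling noise: the closest pair, wild-type replicate 3 and knockout replicate 2, differed by a chi-square of 7.77 per degree of freedom, and other pairs by 26.9 or more.

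From these counts, genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and knockout was tested against wild type with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. The 14508 genes kept were adjusted together by Benjamini-Hochberg with a threshold of 0.05 and no minimum fold. Levels in CPM were counts over TMM-scaled library sizes. Fold changes are knockout over wild type on the log2 scale, with standard errors from the fitted model and 95% intervals. The biological coefficient of variation was 24.2% and the median standard error 0.23. DESeq2 1.42.0 and limma 3.58.1 (voom) were run as alternatives. DESeq2 gave a p for 25668 genes, of which 238 were under 0.05 unadjusted, and left the adjusted p of 23647 rows undefined, which were kept so. The test was tried on simulated data of the same 14508 genes with 50 genes at each of 4 fold sizes; it called 7 unchanged genes. On simulated lists camera called 5 of 5 lists raised 1.5-fold and 0 of 34 untouched lists, with genes simulated as independent of each other.

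Before the data were examined, 51 gene lists were fixed, of pathways, cell types and signs of RNA quality or sex. Lists with at least 5 tested genes were tested, 25 of pathways, 16 of cell types and 7 of quality or sex; 3 had too few detected genes, those of lung epithelium (1 of 11 detected), thymus (2 of 10) and vascular cartilage and valve cells (4 of 12). Camera from limma was used with a preset correlation of 0.01, beside camera with an estimated correlation and fry. Each list's members were also adjusted over the list alone. A list's median, mean and count of higher members describe all its tested genes.

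The genes named in the text follow a rule fixed before the data were examined. It takes Arrdc4, then up to 12 genes per direction past the threshold with a mean log2 CPM of at least 1 and no overlap between groups, filled up to 5 per direction by the smallest p where fewer passed, without predicted, unnamed or sex-linked genes. From each list it takes up to 4 members past the threshold, or up to 2 with the smallest p where none passed. Genes named outside this rule are said to be so, or are members of the clock, epicardial and sex-linked groups described by library and of the Arrdc4 neighbourhood; these and Spp1 were chosen after their values were seen.

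Set before the data were examined as other ways to process the counts were DESeq2's size factors, library size alone, no filter on low counts, a filter of 1 CPM in 3 samples, DESeq2, limma-voom, robust edgeR, each library left out in turn, a replicate block, and for lists an estimated correlation, fry and voom values. Added after the data were seen were a term for Y-linked reads (more than 5 CPM over 4 genes), a term or exclusion for wild-type replicate 3 and knockout replicate 2, an offset for each library's trend on exon length (a spline with 6 degrees of freedom), and lists without Arrdc4. Principal components were taken on log2 CPM of the tested genes.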

Results

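Gene expression was measured by RNA sequencing in 6 mouse hearts of the C57BL/6 background, 3 from wild-type mice and 3 from mice in which Arrdc4 had been knocked out with CRISPR-Cas9. Each heart gave 1 library and the table holds 1 read count per gene and library. The counts summed to 29974501, 37518160 and 35892086 in wild-type replicates 1 to 3 and to 41036626, 31529317 and 36301908 in knockout replicates 1 to 3. Expression levels are given as CPM, a gene's count scaled to a common library size. Between 20108 and 20959 genes had at least 1 count in a library, the genes of the mitochondrial genome took 21.8% to 27.7% of the counts, and the 10 most abundant genes took 27.9% to 31.6%. The single comparison in the design, knockout against wild-type hearts, asks which transcripts differ when Arrdc4 is lost. Arrdc4 is an alpha-arrestin, a family of adaptor proteins that bind NEDD4-type ubiquitin ligases, and its close relative Txnip restrains glucose uptake.

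Arrdc4 transcript was nearly gone from the knockout hearts and was the 1 gene of 14508 tested that passed the threshold. Arrdc4 (ENSMUSG00000042659, GRCm38 chromosome 7, 68736995 to 68749241, minus strand) stood at 9.20 ± 1.60 CPM (SD, n = 3) in wild-type hearts and at 0.0678 ± 0.0432 (SD, n = 3) in knockout hearts. It fell by 6.93 on the log2 scale (SE 0.45, 95% interval -7.99 to -5.87, adjusted p = 0.00226, edgeR quasi-likelihood test). All 3 knockout hearts lay below all 3 wild-type hearts. The wild-type libraries held 349, 307 and 281 Arrdc4 reads and the knockout libraries 5, 1 and 2, so that 0.796% of the wild-type level was left, a 126-fold difference with a 95% counting interval of 63.5 to 292. The counts cover every annotated exon of the gene, 8 in the longer annotated transcript and 5 in the shorter, and do not show which part was deleted. Without knockout replicate 3 the log2 fold change of Arrdc4 was -6.75 and its adjusted p was 0.0519. Its 3 tested neighbours within 1 Mb gave log2 fold changes of 0.02 for Ttc23 (SE 0.16), 0.37 for Synm (SE 0.27) and -0.06 for Igf1r (SE 0.27), and the smallest p among them was 0.643 when adjusted over these 3 genes in edgeR.

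**Figure D1:**
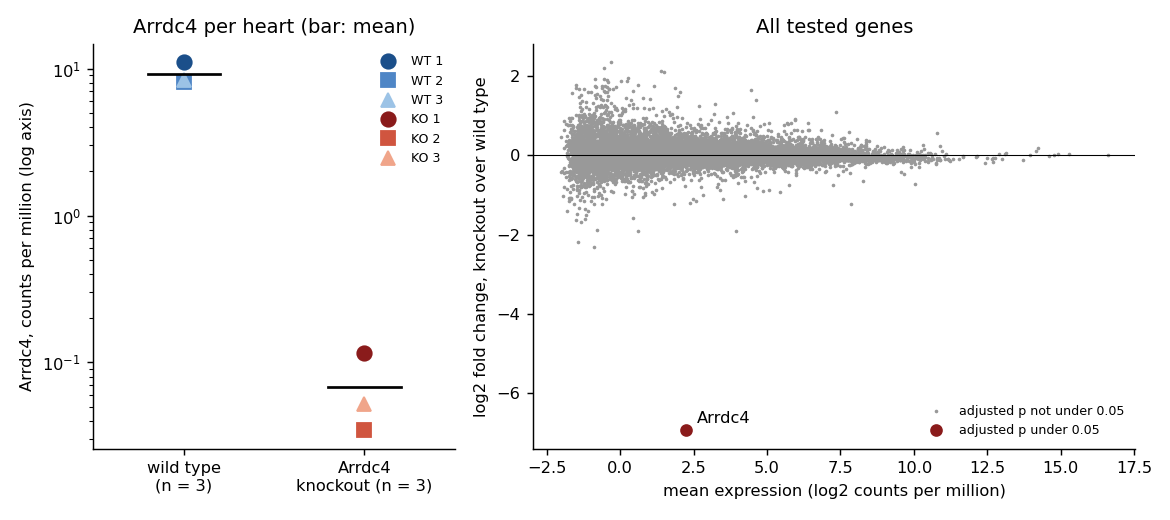
Left, Arrdc4 in CPM on a log axis, with 1 point per heart and a bar at the mean of each group of 3; the wild-type hearts lie between 8.17 and 11.04 and the knockout hearts between 0.0345 and 0.117. Right, log2 fold change (knockout over wild type) against mean log2 CPM for the 14508 tested genes, with 1 point per gene; Arrdc4 stands apart at -6.93.

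No gene was called higher in knockout hearts, and none other than Arrdc4 was called lower. The edgeR test gave 0 higher genes past an adjusted p of 0.05, and DESeq2 and limma-voom also gave 0. At an unadjusted p under 0.05 edgeR held 109 higher and 70 lower genes, 179 in all, where 725 would be expected by chance. That count depended on 1 library: without knockout replicate 2 it was 1126 of 14822 genes, where chance gives 741, and without any other single library it was 94 to 184. It was 624 with wild-type replicate 3 and knockout replicate 2 as a separate level in the fit and 981 of 14610 genes with both left out. The gene with the smallest p after Arrdc4 was Cacng6, a gamma subunit family member of voltage-gated calcium channels, at 2.13 ± 0.117 CPM in wild type and 4.28 ± 0.424 in knockout (SD, n = 3 each; log2 fold change 1.01, SE 0.18). Other genes with higher values in knockout were Zfp365 (log2 fold change 1.66, SE 0.32), Crmp1 (1.65, SE 0.37), Tmem56 (0.86, SE 0.20) and Lrp2bp (0.98, SE 0.24). Lower values were found for Ripor2, an inhibitor of RhoA (-0.80, SE 0.19), Gnb3, a G protein beta subunit (-1.19, SE 0.30), Cyp2b10, a cytochrome P450 (-1.88, SE 0.50), and Rab9b, a small GTPase (-1.60, SE 0.44). None of these 9 genes passed the test, and each had an adjusted p of 1 in edgeR. Some were near the floor in mean CPM, wild type against knockout. These were Zfp365 (0.341 against 1.09), Crmp1 (0.177 against 0.559), Cyp2b10 (0.812 against 0.222) and Rab9b (0.574 against 0.192). In 591 genes (4.07%) the 3 knockout values did not overlap the 3 wild-type values, where chance gives 10%. The 95% interval of the fold change excluded a 2-fold difference in either direction for 11084 genes (76.4%) and a 1.5-fold difference for 5761 (39.7%). In data simulated at this depth and spread, 50 genes were changed at each of 4 fold sizes, with genes drawn as independent. Recovery was 4% at 1.5-fold, 18% at 2-fold, 84% at 4-fold and 100% at 8-fold. Many true changes loosen the Benjamini-Hochberg cutoff, and the simulation left out variation shared between genes. These shares are therefore likely too high for data with 1 gene called.

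In the pathways closest to Arrdc4, no gene other than Arrdc4 passed the test. Of the 30 tested genes of glucose transport and glycolysis, 12 had higher and 18 lower values in knockout, the median log2 fold change was -0.06, and the 95% interval excluded a 2-fold difference for 29 of them. The 2 members with the smallest p were Slc2a12, a glucose transporter (-0.33, SE 0.17), and Pfkfb2, the cardiac form of the enzyme that sets fructose 2,6-bisphosphate (-0.37, SE 0.21). Chosen after their values were seen, the glucose transporters Slc2a1 and Slc2a4 stood at -0.20 (SE 0.17) and -0.09 (SE 0.14). The other tested alpha-arrestins, named on the same terms, stood at 0.17 (SE 0.23) for Arrdc1, -0.33 (SE 0.55) for Arrdc2, 0.10 (SE 0.13) for Arrdc3 and 0.40 (SE 0.40) for Txnip. Of the 5 tested alpha-arrestins, Arrdc4 included, a 2-fold difference was excluded for 2. Txnip reached 527 CPM in knockout replicate 3 and lay between 185 and 272 in the other 5 hearts. Among 44 genes of the vesicle budding machinery 21 were higher and 23 lower, with Cd82 at 0.22 (SE 0.16) and Smpd3, a sphingomyelinase, at 0.43 (SE 0.34), and a 2-fold difference was excluded for 43. Of 12 NEDD4-family ligases and adaptors 8 were higher and 4 lower, with Smurf2 at 0.09 (SE 0.12), and a 2-fold difference was excluded for all 12. The 39 genes of the unfolded protein response split into 19 higher and 20 lower, with Ddit4 at -0.75 (SE 0.31) and Ddit3 at 0.38 (SE 0.19), and a 2-fold difference was excluded for 33.

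Heart muscle genes gave no list called by camera, a test of whether a list's genes shift against all other genes. The 27 sarcomere genes had a median log2 fold change of -0.05, with Myom2 at -0.48 (SE 0.29), and camera gave an adjusted p of 0.386. The 15 genes of cardiac stress had a median of 0.11, with the beta myosin heavy chain gene Myh7 at 0.36 (SE 0.26), and an adjusted p of 0.762 in camera. The 43 genes of calcium handling and ion channels had a median of 0.10, with the potassium channel Kcnq1 at 0.31 (SE 0.15) and the calcium channel Cacna1h at 0.61 (SE 0.30), and an adjusted p of 0.292 in camera. Fatty acid uptake and oxidation had a median of -0.04 over 41 genes, 30 of them lower, with an adjusted p of 0.163 in camera. Cardiomyocyte markers had a median of -0.06 over 15 genes and ventricular markers -0.09 over 8 genes, with adjusted p values of 0.61 and 0.184 in camera. When 1 library was left out, list means took both signs for sarcomere (-0.099 to 0.053), cardiac stress (-0.195 to 0.204), fatty acid (-0.076 to 0.025) and cardiomyocyte genes (-0.044 to 0.071). They kept 1 sign for calcium handling (0.04 to 0.121) and ventricular genes (-0.243 to -0.015). Apart from Arrdc4 in the alpha-arrestin list, no member of any of the 48 tested lists passed over all genes tested or when adjusted over the list alone. The smallest such p was 0.0800 in edgeR, for Npr3, a natriuretic peptide receptor of the endocardium (log2 fold change -0.49, SE 0.14).

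Camera called 14 of the 48 lists, 7 up and 7 down, with its preset correlation between genes of 0.01. None was called with an estimated correlation, where the smallest adjusted p was 0.153, and fry gave a smallest adjusted p of 0.443. Cell cycle genes had the largest upward median of the pathway lists: 27 of 29 were higher in knockout, the median log2 fold change was 0.93, and the adjusted p was 3.36e-12 in camera and 0.856 with an estimated correlation. Top2a, which untangles DNA at mitosis, stood at 2.11 (SE 0.84) and the mitotic gene Birc5 at 1.70 (SE 0.59). Birc5 was near the floor, with a mean of 0.272 CPM in wild type and 0.874 in knockout. Under the filter of 1 CPM in 3 samples the cell cycle list's mean was 0.59, against 0.87 in the main fit. Knockout replicate 1 was the highest of the 6 hearts for 24 of these 29 genes. Chance gives 16.7% for a heart named in advance and genes that vary independently, and neither can be assumed here. Without that heart the list's mean was 0.21, against 0.87 with all 6 hearts, and its adjusted p was 0.0367 in camera. Matrix genes (40 of 44 higher, median 0.62, camera adjusted p = 6.02e-09) included Lum, a collagen-binding proteoglycan (0.75, SE 0.24), and Postn, a matrix protein of activated fibroblasts (1.63, SE 0.68). Fibroblast markers (17 of 18 higher, median 0.33, camera adjusted p = 1.34e-05) included Smoc2 (0.56, SE 0.21), and markers of epicardial and mesothelial cells (13 of 14 higher, median 0.96, camera adjusted p = 3.61e-05) included Aldh1a2, a retinoic acid synthase (0.93, SE 0.42), and Lrrn4 (1.86, SE 0.90). The adjusted p was 0.856 with an estimated correlation for matrix, fibroblast and epicardial genes alike. Knockout replicate 1 was the highest heart for 32 of 44 matrix genes and 13 of 14 epicardial markers. Without it the adjusted p in camera was 0.783 for matrix, 0.177 for fibroblast and 0.965 for epicardial genes, and their means were 0.15, 0.16 and 0.19 against 0.59, 0.40 and 0.93 with all 6 hearts. The means were larger without knockout replicate 2, at 1.17 for cell cycle, 0.92 for matrix, 0.64 for fibroblast and 1.31 for epicardial genes, and without wild-type replicate 2 they were 0.78 for matrix and 0.60 for fibroblast genes.

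The other lists called up were interferon-stimulated genes, pericyte and smooth muscle markers and beta-adrenergic signalling. Of 46 interferon-stimulated genes 39 were higher, with a median of 0.22 and Ifit3b at 0.72 (SE 0.28), and the adjusted p was 4.02e-06 in camera and 0.859 with an estimated correlation. Without knockout replicate 1 their mean was -0.03 and the adjusted p was 0.794 in camera, and without knockout replicate 3 the mean was 0.38 against 0.23 with all 6 hearts. Pericyte and smooth muscle markers had a median of 0.24 over 14 genes, with Tagln at 0.26 (SE 0.22), and an adjusted p of 0.0165 in camera, 0.856 with an estimated correlation and 0.625 without knockout replicate 1. That p was 0.143 without knockout replicate 3, 0.0613 without wild-type replicate 1 and 0.0537 without wild-type replicate 3, with means of 0.23, 0.24 and 0.25 against 0.29 with all 6 hearts and 0.11 without knockout replicate 1. It was 0.000318 without knockout replicate 2 (mean 0.48) and 0.0109 without wild-type replicate 2 (mean 0.42). Beta-adrenergic signalling genes were higher for 20 of 23, with a median of 0.12 and the receptor Adrb1 at 0.25 (SE 0.14), and their adjusted p was 0.0176 in camera, 0.859 with an estimated correlation and 0.305 without knockout replicate 1. It was 0.401 without knockout replicate 3, and 0.0623 and 0.178 without wild-type replicates 2 and 3, with means of 0.07, 0.15 and 0.09 against 0.12 with all 6 hearts and 0.06 without knockout replicate 1. Without knockout replicate 2 it was 0.00394 (mean 0.22).

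Among lists called down, genes of ketone and branched-chain amino acid catabolism were lower for 23 of 23, with a median of -0.14 and Dbt, a subunit of the branched-chain ketoacid dehydrogenase, at -0.26 (SE 0.15). Their adjusted p was 2.33e-05 in camera, 0.856 with an estimated correlation and 0.184 without knockout replicate 1, where their mean was -0.06 against -0.14 with all 6 hearts and -0.23 without knockout replicate 2. Citric acid cycle genes were lower for 21 of 24, with a median of -0.09 and Got1 at -0.31 (SE 0.16), and their adjusted p was 0.0073 in camera, 0.856 with an estimated correlation and 0.58 without knockout replicate 1. Their mean was -0.09 with all 6 hearts, -0.02 without knockout replicate 1 and -0.18 without knockout replicate 2. The 75 nuclear genes of the respiratory chain were all lower, with a median of -0.09, Ndufa10 at -0.10 (SE 0.14) and an adjusted p of 0.000679 in camera. That p was 0.924 with an estimated correlation, and the mean turned to 0.07 without knockout replicate 1, 0.15 without wild-type replicate 3 and 0.03 without knockout replicate 3, with adjusted p values of 0.372, 0.148 and 0.5 in camera. The mean was -0.09 with all 6 hearts and -0.44 without knockout replicate 2, -0.23 without wild-type replicate 2 and -0.17 without wild-type replicate 1. Replication-dependent histone genes were lower for 7 of 8, with a median of -0.25 and Hist1h1e at -0.99 (SE 0.30), and their adjusted p was 0.000126 in camera, 0.856 with an estimated correlation and 0.00144 without knockout replicate 1. Their mean was -0.29 with all 6 hearts and -0.14, -0.13 and -0.14 without wild-type replicate 1, wild-type replicate 3 and knockout replicate 3, with adjusted p values of 0.0179, 0.0265 and 0.0466 in camera, and it was -0.48 without knockout replicate 2 and -0.41 without wild-type replicate 2. They stood highest in wild-type replicate 3 (0.39) and knockout replicate 2 (0.37), relative to each gene's mean, and between -0.41 and 0.14 in the other hearts. Genes that respond to glucocorticoids and fasting had a median of -0.06 over 27 genes, with Lcn2 at -1.23 (SE 0.46), and their adjusted p was 0.0235 in camera and 0.859 with an estimated correlation. Without wild-type replicate 2 their mean was 0.09, and without knockout replicate 2 it was -0.03, with adjusted p values of 0.626 and 0.824 in camera, against -0.13 with all 6 hearts, -0.27 without knockout replicate 3 and -0.25 without wild-type replicate 1. The alpha-arrestin list was called down through Arrdc4 itself: its median over 5 genes was 0.10, its mean was -1.32, and its adjusted p was 1.99e-17 in camera and 0.153 with an estimated correlation. The 5 neutrophil markers had a median of 0.10 and a mean of -0.24, with an adjusted p of 0.0473 in camera and 0.856 with an estimated correlation. Without knockout replicate 3 the mean was 0.12 and the adjusted p was 0.963 in camera, and the p was 0.199 without wild-type replicate 3 (mean -0.16) and 0.0604 without knockout replicate 2 (mean -0.66). The call was kept without knockout replicate 1 (adjusted p = 0.000275 in camera, mean -0.45). It was also kept without wild-type replicates 1 and 2 (0.0483 and 0.0474, means -0.30 and -0.18). With an offset for each library's length trend the adjusted p in camera was 0.0805 for neutrophil markers (mean -0.29), 0.0567 for glucocorticoid- and fasting-responsive genes (mean -0.15) and 0.0845 for beta-adrenergic signalling (mean 0.08). Median and camera direction differed in sign for 10 of the 48 lists, the alpha-arrestins and neutrophil markers included. Some lists share genes, so their calls are not independent. Members also found in other lists were 15 of 27 glucocorticoid- and fasting-responsive genes and 3 of 5 neutrophil markers, Lcn2 in both. The same held for 8 of 44 matrix genes and 5 of 18 fibroblast markers, Lum in both.

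**Figure D2:**
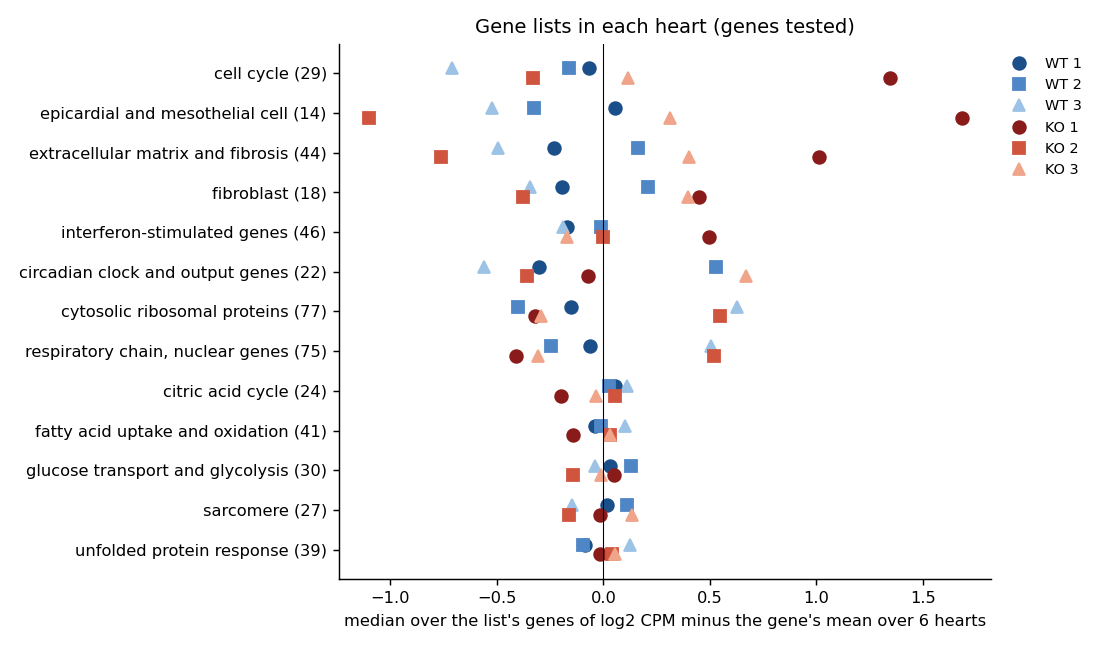
Median over each list's genes of log2 CPM minus the gene's mean over the 6 hearts, with 1 point per heart and the number of tested genes in brackets; blue marks are wild type and red marks knockout. Knockout replicate 1 stands at 1.34 for cell cycle and 1.68 for epicardial genes, and wild-type replicate 3 and knockout replicate 2 stand together at 0.63 and 0.55 for cytosolic ribosomal protein genes.

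Expression differed widely between hearts of the same genotype. The leading component of expression held 58.9% of the variance and set wild-type replicate 3 (score -42.4) and knockout replicate 2 (-43.8) apart from knockout replicate 1 (38.3), wild-type replicate 2 (25.2) and knockout replicate 3 (24.6), with wild-type replicate 1 (-1.88) between them. Ribosomal protein genes, 77 in number, stood at 0.63 and 0.55 in the first 2 of these hearts and between -0.40 and -0.15 in the others, and nuclear genes of the respiratory chain at 0.51 and 0.52 against -0.41 to -0.06. Of the signs of RNA quality among the lists, the same 2 hearts were highest for genes of the mitochondrial genome (0.19 and 0.25 against -0.25 to 0.01), replication-dependent histones (0.39 and 0.37 against -0.41 to 0.14) and nuclear-retained noncoding RNAs (0.25 and 0.27 against -0.30 to 0.03), and not for immediate early genes (-0.23 and -0.21 against -0.23 to 0.39). They also had the largest shares of mitochondrial counts, 26.2% and 27.7% against 21.8% to 25.7%. Across genes, which are not independent replicates, expression relative to the mean of the 6 hearts correlated negatively with exon length in those 2 hearts (Spearman rho -0.447 and -0.427) and positively in wild-type replicate 2, knockout replicate 1 and knockout replicate 3 (0.351, 0.309 and 0.384), with 0.0632 in wild-type replicate 1. With these 2 hearts as a separate level in the fit, an alternative chosen after the data were seen, Arrdc4 was still the 1 gene called (log2 fold change -6.94, adjusted p = 0.000248 in edgeR). With both left out, Spp1, which encodes osteopontin, was called beside Arrdc4, at a log2 fold change of 6.09 (adjusted p = 0.0029 in edgeR). Spp1 stood at 0.19, 0.426 and 27.0 CPM in wild-type replicates 1 to 3 and at 22.7, 4.58 and 21.2 in knockout replicates 1 to 3.

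**Figure D3:**
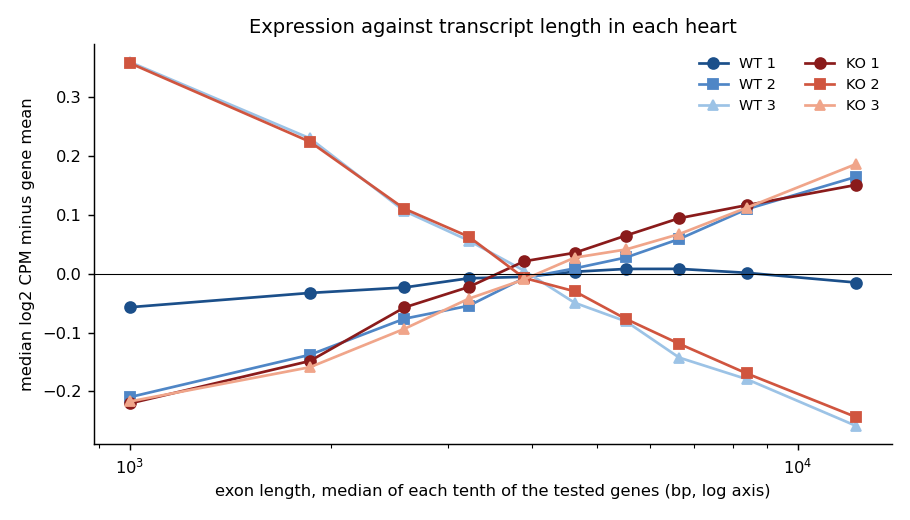
Median log2 CPM relative to the gene's mean over the 6 hearts (vertical axis) against the median exon length in base pairs of 10 equal sets of the tested genes (log axis), with 1 line per heart. Wild-type replicate 3 and knockout replicate 2 start at 0.36 for the shortest genes and end at -0.26 and -0.24 for the longest, and 3 of the other hearts run the opposite way.

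Sex-linked transcripts divided the hearts within both genotypes, but not evenly. Y-linked reads were found in 2 wild-type hearts and 1 knockout heart, so this division and genotype are partly confounded. The 4 Y-linked genes summed to 150 and 146 CPM in wild-type replicates 1 and 2 and to 158 in knockout replicate 1, and to between 1.19 and 2.24 in the other 3 hearts. Xist, which silences an X chromosome in females, stood at 39.5 to 50.1 in the latter and at 0.293 or less in the former. Arrdc4 differed by genotype within both sets of hearts, at 11.04 and 8.17 against 0.117 CPM in those with Y-linked reads and at 8.39 against 0.0345 and 0.0524 in those without, and each set holds too few hearts for a test. With a term for Y-linked reads, chosen after the data were seen, 539 genes had an unadjusted p under 0.05 in edgeR, against 179 without it. Camera then called 16 lists, and 12 of the 14 called in the main fit were among them.

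Genes of the circadian clock also varied within genotypes. Dbp, an output gene of the clock, stood at 84.6 CPM in wild-type replicate 2 and 142 in knockout replicate 3, and between 10.5 and 31.8 in the other 4 hearts. Per1 and Per2, repressors of the clock, were likewise highest in these 2 hearts, Per1 at 68.5 and 36.6 and Per2 at 8.1 and 11.9. Arntl, the activator that peaks in the opposite phase, was lowest in them, at 5.78 and 2.1 against 15 to 23.8. The 22 clock and output genes had a median log2 fold change of 0.13 between genotypes, and the adjusted p in camera was 0.61.

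**Figure D4:**
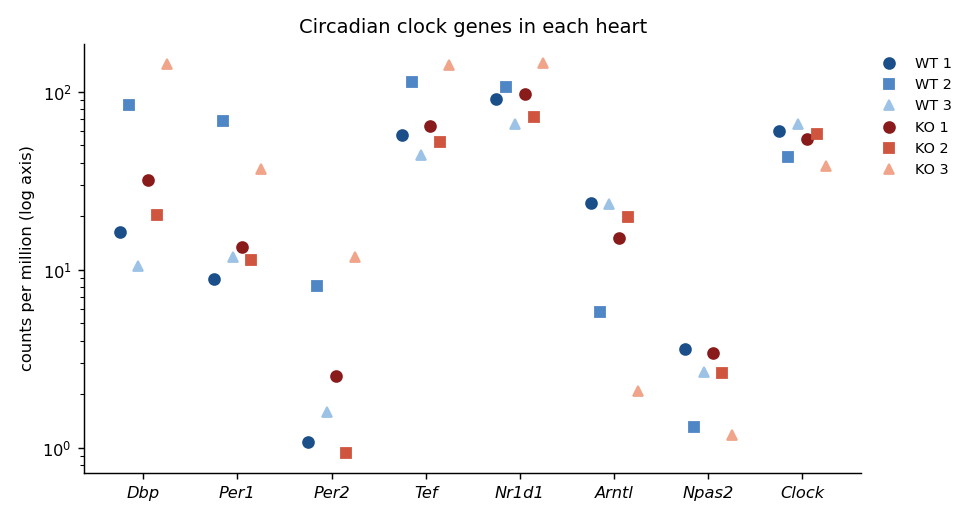
CPM on a log axis for 8 clock genes, with 1 point per heart; blue marks are wild type and red marks knockout. Wild-type replicate 2 and knockout replicate 3 are highest for Dbp, Per1 and Per2 and lowest for Arntl, Npas2 and Clock.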

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

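The term for Y-linked reads, the term or exclusion for wild-type replicate 3 and knockout replicate 2, the length offset and the lists without Arrdc4 were chosen after seeing the data. Arrdc4 was lower in every setting, and it was the 1 gene called by edgeR under both other scalings, both filters, robust estimation, the Y-linked term, the length offset and the library pair term, and by DESeq2 and limma-voom. Its log2 fold change ran from -7.58 to -6.68 when 1 library was left out, where 0 to 1 genes were called, all of them lower; 0 were called without knockout replicate 3, with fewer samples, where the adjusted p of Arrdc4 was 0.0519. With the replicate block it was -7.00 with an adjusted p of 0.0507, 0 genes were called and 0 were lower; over all alternatives that p ran from 1.28e-29 (DESeq2) to 0.0519. Deviations over genes showed no pairing by replicate number. Same-numbered hearts correlated at 0.184, -0.649 and -0.399, and wild-type replicate 3 went best with knockout replicate 2 (0.684). The leading component enters these correlations, so a weaker pairing could be hidden. The block leaves fewer degrees of freedom and kept all 14 list calls. With wild-type replicate 3 and knockout replicate 2 both left out, 2 genes were called and 1 was higher (Spp1). The wild-type heart left out held the most Spp1 of all hearts, 27.0 CPM, against 0.19 and 0.426 in the other wild types. The call depends on leaving both hearts out, since 0 genes were called higher without either one alone. Why that wild-type heart differs was not tested. Of 97 other named genes, 91 kept their sign in every setting that gave a value, 9 of 1732 values changed sign, and 0 passed; the filter of 1 CPM gave none for those it removed.

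Of 14 lists, 0 were called with an estimated correlation, 0 with fry, 0 with the length offset and an estimated correlation, and 0 with the library pair term and an estimated correlation. Leaving out 1 library gave 8 to 17 lists, the lowest without knockout replicate 1 (5 shared, 1 up). That setting leaves no knockout heart with Y-linked reads, against 2 wild-type hearts with them, so genotype and these reads are then more strongly confounded. In every preset-correlation setting that tested them, 3 lists kept their call: alpha-arrestins, cell cycle and histones. The neutrophil call ended with DESeq2's size factors (adjusted p = 0.0571), voom values (0.0582), the Y-linked term (0.221), the length offset (0.0805), the library pair term (0.107) and that pair left out (0.11), at means of -0.60 to -0.25 against -0.24. The glucocorticoid and fasting call ended with no filter (0.0636), voom values (0.0582), the Y-linked term (0.221), the length offset (0.0567), the pair term (0.0538) and the pair left out (0.435), at means of -0.15 to -0.07 against -0.13. The beta-adrenergic call ended with no filter (0.0504, mean 0.05) and the length offset (0.0845, mean 0.08 against 0.12). Directions changed in 125 of 1005 list values. When 1 library was left out, camera's direction changed with a call gained or lost, over means given here, for the respiratory chain (-0.44 to 0.15), interferon-stimulated genes (-0.026 to 0.375), immediate early genes (-0.21 to 0.36), glucocorticoid- and fasting-responsive genes (-0.272 to 0.091), ribosomal proteins (-0.41 to 0.30), endothelial cells (-0.11 to 0.24) and macrophages (-0.20 to 0.45). The mean alone changed sign, with a call lost or gained, for neutrophil markers (-0.66 to 0.12) and insulin signalling (-0.10 to 0.14). The causes were not tested. At 29974501 to 41036626 counts per library the median standard error of a log2 fold change was 0.23; how far more depth would lower it was not tested.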

Other observations

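The tests of sex, of length as the whole cause, of the knockout genotype, of time of day and of the splits for genes were chosen only after the result was seen. Blood and immune markers varied between single hearts of both genotypes. Neutrophil markers, 5 genes, stood at a median of -1.29 in knockout replicate 3 and between -0.18 and 0.58 in the other 5 hearts, relative to each gene's mean. Macrophage and monocyte markers were higher for 16 of 19 genes, with Ccr2, a receptor of recruited monocytes, at a log2 fold change of 1.12 (SE 0.45), and they stood at 0.77 in knockout replicate 1 and between -0.44 and 0.19 in the others. Without that heart their mean log2 fold change was -0.20. Lymphocyte markers were higher for 9 of 9 genes, with a median of 0.22, Igkc at 0.86 (SE 0.69) and an adjusted p of 0.22 in camera. When 1 library was left out their mean ran from -0.22, without wild-type replicate 2, to 0.43, without wild-type replicate 3, so the direction depended on single hearts. They stood at 0.45 to 0.52 in wild-type replicate 1 and knockout replicates 1 and 2, and at -0.70 to -0.09 in the other 3 hearts. Skeletal muscle genes had a median of -0.17 over 10 genes, and erythroid and platelet genes 0.05 over 11, neither called by camera (adjusted p = 0.642 and 0.983).

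Wild-type replicate 3 and knockout replicate 2 shared a profile rich in ribosomal protein and respiratory chain transcripts, on a component that held 58.9% of the variance, and were also highest for genes of the mitochondrial genome (0.19 and 0.25, others up to 0.01), histones (0.39 and 0.37, others up to 0.14) and nuclear-retained RNAs (0.25 and 0.27, others up to 0.03). The tables argue against GC content, since removing each library's trend on it took away 7.6% of the variance along that component. They argue against sex as the whole cause, since 1 heart without Y-linked reads, knockout replicate 3, lay on the other side. A part played by sex stays open, since both hearts of the pair were also without Y-linked reads. Removing each library's trend on exon length took away 34.9%, and a leading component with 54.1% of the variance was left that set the same 2 hearts apart, which argues against length as the whole cause. A bias for short transcripts may be part of it, but the 34.9% lay between the bounds of 25% and 50% set before the test, so how much of it stays open. RNA quality stays open, since these last 3 lists, fixed as signs of it, moved with the pair; dissection and processing day were not tested, and genotype cannot set apart a pair with 1 heart of each.

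Cell cycle, matrix and epicardial genes stood higher in knockout replicate 1 than in the mean of the other 5 hearts, by medians of 1.61, 1.21 and 2.02 on the log2 scale. Length bias is argued against for the cell cycle genes, since 98.7% of their excess was left with length trends removed. A knockout effect alike in every heart is argued against as the whole cause for the cell cycle genes. Their median in knockout replicate 1 lay 1.23 above the highest other knockout, where the other 5 hearts spanned 0.83. The gaps of 0.61 for matrix and 1.37 for epicardial genes lay within spans of 1.16 and 1.41 and decide nothing. Knockout replicate 1 was also the only knockout heart with Y-linked reads, so a knockout effect limited to such hearts stays open. A part may come from the genotype and stays open. Without knockout replicate 1 the means were 0.21, 0.15 and 0.19, and 1 of the 3 lists, the cell cycle, was called. That setting keeps knockout replicate 2, whose medians relative to each gene's mean, -0.33, -0.76 and -1.10, lay below wild-type replicates 1 and 2. Those of knockout replicate 3, 0.12, 0.40 and 0.31, lay above all wild-type hearts. With wild-type replicate 3 and knockout replicate 2 both left out the means were 1.04, 0.92 and 1.16, with knockout replicate 1 still included. Age and the amount of epicardial tissue in the sample were not tested. In knockout replicate 1, 13 of 14 epicardial markers, none in another list, were highest, such as Msln at 6.76 CPM against 0.276 to 2.80. Clu, the most abundant and also expressed by other heart cells, was not, at 540 against 408 to 611.

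Clock genes differed between hearts of 1 genotype, and over all 6 hearts Dbp had a range of 3.75 on the log2 scale. Length bias is argued against for Dbp, since 103% of that range was left with length trends removed. Other clock genes were not tested in this way. Different times of collection may lie behind the differences between hearts. The medians of 9 output genes and of 3 genes of the opposite phase gave a Spearman rho of -0.543 over the 6 hearts (exact permutation p = 0.297, two-sided). Their Pearson r was -0.95 (exact permutation p = 0.0431, two-sided). The rank test missed the p of 0.05 set for it, so the time of day stays open. Genotype cannot set apart hearts of 1 genotype, such as wild-type replicate 2, at 84.6 CPM of Dbp, and the other wild types, at 16.3 and 10.5.

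The 6 hearts allow 10 splits into groups of 3, too few for a share under 0.05. For genes past the threshold, 3 of the 10 splits, the real one included, gave at least the 1 gene of the real split, and the highest other gave 4039. That split sets wild-type replicates 1 and 3 and knockout replicate 2 against the rest and points to a structure of the samples, the leading component. The split along Y-linked reads gave 5 genes, but it is defined by tested genes themselves and so says nothing about chance. With a term for these reads Arrdc4 had a log2 fold change of -6.85. For gene lists called by camera, 8 of the 10 splits, the real one included, gave at least the 14 lists of the real split, and the highest other gave 21.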
